A study of Homo sapiens with 4 samples.

How the data were processed

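RNA was profiled by sequencing in 4 libraries of HCT116, a cell line derived from a human colorectal carcinoma. Per the labels, 2 libraries came from wild-type cells and 2 from cells in which PHGDH had been knocked out. The titles number the libraries 1 and 2 within each genotype. Per the labels' protocols, cells grew in DMEM with 10% bovine calf serum, and each library was made from 1 μg of total RNA with the TruSeq V2 kit, which selects polyadenylated RNA, through 12 cycles of PCR, and was read as 2x150 pairs. The kit as named does not mark the strand of origin, so transcripts that overlap on opposite strands cannot be separated. Nothing in the labels says whether the libraries of one genotype came from separate cultures, or whether the knockout libraries came from one clone or from several. All p-values therefore measure only the spread between these libraries, which may be technical, and an effect of the knockout cannot be separated from a difference between clones.

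The authors deposited 1 table per library with a gene identifier, a gene name, a locus and a value in FPKM, which are fragment numbers divided by the length of the transcript and by the number of mapped fragments, per the file headers. Not every gene is listed for each library, and why a gene is left out is not stated. A gene missing from a library entered as 0, which need not mean that it had no signal. The tables listed 26046 genes in at least 1 library and 17702 genes in all 4. The submitters' processing notes name Bowtie 0.12.2 and the mouse build mm8. That build does not describe these tables: 25849 of the identifiers occurred in human GENCODE release 29, 25823 of them lay on the same GRCh38 chromosome, and 14790 had a GENCODE start exactly 1 base above the start in the table. The loci were therefore read as GRCh38 with a start counted from 0, and 1 was added for printing. Genes that overlap are given one joint locus in the tables, so a printed interval can be wider than the gene. The program that computed the FPKM, its annotation release, its filters and its use of strand are not given in the sources used here.

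FPKM values are not counts and carry no stated depth. Low values of genes with a longest transcript of at least 1000 nt were searched for the step that 1 fragment is worth. The best steps implied 20.3 and 22.6 M fragments (M, mega) in the wild-type libraries and 22.6 and 19.3 M in the knockout libraries. With these steps, 59.4% to 70.2% of the low values lay within 0.2 steps of a whole number of fragments. Evenly spread values would give 40%, but the steps were fitted to these same values, which raises the share. The implied depths are therefore rough estimates, and no count test was run. The design fixed before the data were examined had provided a count model and, for normalized values, the test used here.

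Values were transformed to log2(FPKM + 1). Genes at 1 FPKM or more in at least 2 of the 4 libraries were tested, 13072 in all, of which 11690 were protein-coding. Among the tested genes, 45 were missing from at least 1 table, and 5 of these were among the genes that passed the test below. Knockout and wild type were compared with limma 3.58.1 in R 4.3.3, with moderated variances that followed the mean expression and were estimated robustly, and with Benjamini-Hochberg adjustment. The fit had 2 residual degrees of freedom and a median of 3.14 prior degrees of freedom. A gene passed at an adjusted p of 0.05 or less. Fold changes are given as log2 differences on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM, with the standard error of the model; ratios of mean FPKM are given beside some of them. SDs are over the 2 libraries of a group.

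Before the data were examined, 23 gene lists with 675 distinct genes were fixed. They covered serine and one-carbon enzymes, amino acid stress, neighbouring metabolism, stress responses, proliferation, colon and mesenchymal markers, and markers of cell types foreign to the line. Of these genes, 568 were tested. The 21 lists with at least 5 tested members were compared with all other tested genes by camera, limma's competitive set test, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated per list, and fry, which tests whether the genes of a set move on balance in one direction, were run beside it. With an estimated correlation camera uses the 2 residual degrees of freedom of the fit and has little power. A call lost there need not reflect correlation between genes. For each list the number of passing genes is also given after adjustment over the list alone.

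The genes named in the text were set by a rule fixed before the data were examined: PHGDH; the 10 largest rises and the 10 largest falls among passing genes with both knockout values on one side of both wild-type values and a group mean of at least 5 FPKM, leaving out unnamed loci; for each list up to 4 passing members with the largest change and a group mean of at least 1 FPKM; and PSAT1, PSPH, SHMT1, SHMT2, MTHFD2, ATF4 and ASNS whatever their values. The rule gave 74 genes. Genes outside it are marked as chosen after their values were seen. Some genes that the rule gave are not reported here.

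The fit and the set test were tested on simulated data with the means and spread of the 13072 genes, in which 200 genes were changed. Of these, 78% were recovered at a log2 change of 1 and 97% at a log2 change of 2, none with the wrong sign. Of the simulated calls, 7.41% were false. The simulated errors were normal, independent between genes and equally wide in both groups. The simulation therefore could not show how the fit and the set test behave with correlated genes or unequal spreads.

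The alternatives fixed beforehand were the replicate number as a block, quantile normalization, scaling by median ratios, no filter on low values, a mean of at least 5 FPKM, leaving out each library, limma without its trend and robust options, pseudocounts of 0.1 and 5, a log2 change of at least 1, and the other set tests. Added after seeing the data were the removal of a trend with transcript length and GC content per library, a fit of protein-coding genes with a longest transcript of at least 1000 nt, and the omission of either wild-type library together with median-ratio scaling. Lengths and GC contents came from GENCODE release 29 and covered 99.7% of the tested genes. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.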

Results

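HCT116 cells, an epithelial line from a human colorectal carcinoma, were profiled by polyadenylated RNA sequencing with intact PHGDH and after knockout of PHGDH, the enzyme that starts serine synthesis from the glycolytic intermediate 3-phosphoglycerate. There were 2 wild-type and 2 knockout libraries. The deposited FPKM tables listed 22630 and 20761 genes in the wild-type libraries and 21157 and 20871 in the knockout libraries, and the depths implied by their low values ran from 19.3 to 22.6 M fragments (M, mega). Over the 13072 tested genes, the libraries of a genotype correlated with a Pearson coefficient across genes of 0.977 in wild type and 0.989 in knockout. Wild-type replicate 1 stood apart: its FPKM summed to 528661, against 415772 to 436366 in the other 3 libraries, and it held 901 non-coding genes with a longest transcript under 1000 nt at 1 FPKM or more, against 372 to 400 in the others. The log2 difference between the replicates had an SD over genes of 0.379 in wild type and 0.252 in knockout. Transcripts of the mitochondrial genome took 11.4% and 10.5% of the FPKM in wild-type replicates 1 and 2 and 12.7% and 10.9% in knockout replicates 1 and 2.

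PHGDH itself (ENSG00000092621, a protein-coding gene at 119659798 to 119744215 of chromosome 1, GRCh38) was measured first. Its level was 105 and 108 FPKM in the wild-type libraries and 29.4 and 31.6 FPKM in the knockout libraries. The mean fell from 107 ± 2.10 (SD, n = 2) to 30.5 ± 1.61 FPKM (SD, n = 2), a 3.5-fold lower level and a log2 change of -1.78 ± 0.10 (SE; adjusted p = 0.00758, limma). The transcript remained measurable in both knockout libraries; a knockout can leave a transcript that makes no working protein, and the tables give no values for parts of the gene.

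The comparison of knockout with wild type asked which transcripts differ when PHGDH is lost. The changes ran in both directions: 307 genes were higher and 277 lower in the knockout, together 4.47% of the 13072 tested (limma, adjusted p at or under 0.05), and 165 and 133 of these changed by a log2 of at least 1. Most were protein-coding (557 of the 584). The counts depended on the processing: they were 1047 and 694 with quantile normalization, 999 and 846 with median-ratio scaling, 878 and 782 after removal of a trend with transcript length and GC content, and 5 and 12 without a filter on low values. With the replicate number as a block they were 28 and 36. They also depended on single libraries: they were 960 and 653 without wild-type replicate 1, 851 and 2835 without wild-type replicate 2, and 0 and 0 without knockout replicate 1 and again without knockout replicate 2, where limma gave 1475 and 1598 genes in both directions together at an unadjusted p under 0.05. The 584 genes kept their direction in each of these fits, but all 584 had both knockout values on one side of both wild-type values. Leaving out a library or the filter could therefore not turn their direction.

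Among the 10 largest rises, EHF, an epithelial transcription factor of the ETS family, rose 8.47-fold, from 6.86 ± 1.25 to 58.1 ± 4.13 FPKM (SD, n = 2 each; log2 change 2.92 ± 0.15, SE; adjusted p = 0.00654). MAN1A1, a mannosidase that trims N-glycans in the Golgi, rose from 20.9 to 126 FPKM (log2 change 2.54 ± 0.11, adjusted p = 0.00428). CYP24A1, the enzyme that inactivates vitamin D, rose from 12.1 to 72.3 FPKM (log2 change 2.50 ± 0.17), and DHRS3, a retinaldehyde reductase, from 3.68 to 21.3 FPKM (2.25 ± 0.14). ID3, an inhibitor of basic helix-loop-helix transcription factors, rose from 25.2 to 112 FPKM (2.10 ± 0.10). APOBEC3G and APOBEC3F, cytidine deaminases that restrict retroviruses and lie side by side on chromosome 22, rose from 0.758 to 10.8 FPKM (2.74 ± 0.21) and from 5.79 to 29.2 FPKM (2.15 ± 0.13). The other genes of this set were ZNF704 (2.71), DDIT4L (2.56), an inhibitor of mTOR signalling, and VSNL1 (2.13), a neuronal calcium sensor.

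Among the largest falls were an intermediate filament gene, enzymes of nucleoside metabolism and interferon-induced genes. KRT7, a keratin of simple epithelia, fell from 37.5 ± 5.17 to 1.22 ± 0.05 FPKM (SD, n = 2 each), a 30.7-fold lower level with a log2 change of -4.11 ± 0.15 (adjusted p = 0.00376). NT5E, the surface 5'-nucleotidase that makes adenosine, fell from 61.9 to 4.94 FPKM (log2 change -3.41 ± 0.12), and UPP1, which cleaves uridine to uracil and ribose 1-phosphate, from 68 to 6.82 FPKM (-3.14 ± 0.12). DKK1, a secreted inhibitor of WNT signalling, fell from 297 to 49.5 FPKM (-2.56 ± 0.11, adjusted p = 0.00428). The other 6 were OASL, IFI44, IFIT1, IFIT2, IFIT3 and ISG15, described with the interferon list. The plot of FPKM per library shows the 20 genes beside PHGDH.

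**Figure D1:**
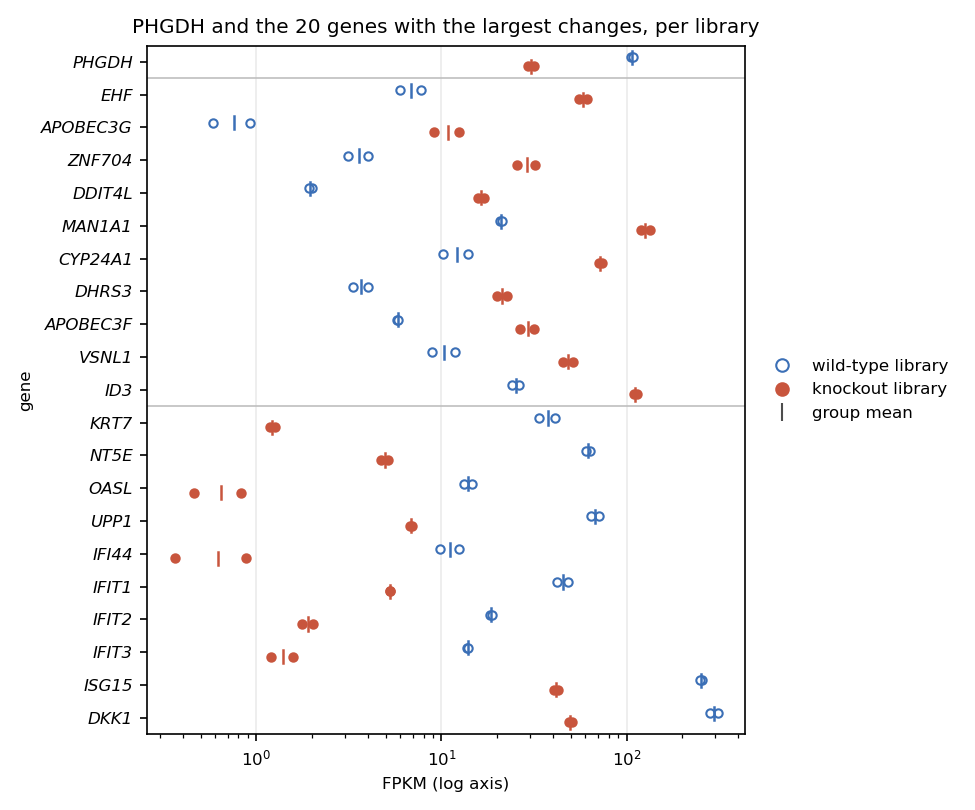
FPKM (log axis) of PHGDH, of the 10 genes with the largest rise and of the 10 with the largest fall in each of the 4 libraries, with open points for wild type, filled points for knockout and vertical ticks for the mean of the 2 libraries of a group. The points of the groups do not overlap for any gene shown; PHGDH lies at 105 and 108 FPKM in wild type and at 29.4 and 31.6 FPKM in knockout.

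Several of these genes share a joint locus in the tables with an overlapping or neighbouring gene, and their values are uncertain to the extent that fragments could be assigned to either: APOBEC3F with APOBEC3G, KRT7 with KRT81, IFIT1, IFIT2 and IFIT3 with each other and with LIPA, DDIT4L with H2AFZ, and MAN1A1 with a non-coding gene. Of the genes named below, the same holds for MTHFD2 with DCTN1, DDIT3 with MARS and GLI1, KRT18 with KRT8, CCND1 with ORAOV1, WARS with WDR25, ALDOC, TXNRD1, TM7SF2, SREBF2, PFKP, VEGFA, BNIP3L, LOXL2, NPC2 and SHMT1. APOBEC3 genes, keratins and FTH1 also have paralogs or pseudogenes of similar sequence.

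PSAT1, which acts next after PHGDH in serine synthesis, was lower too, while PSPH and most one-carbon enzymes did not pass over all genes. Of 27 tested members of the serine and one-carbon list, 3 fell (PHGDH, PSAT1 and MTHFD2) and none rose; adjusted over the list alone, 6 fell and 1 rose. The aminotransferase gene PSAT1 fell from 246 ± 2.00 to 105 ± 3.17 FPKM (SD, n = 2 each; log2 change -1.23 ± 0.10, SE; adjusted p = 0.0151, limma). MTHFD2, a mitochondrial folate enzyme, fell from 295 ± 43.9 to 144 ± 1.91 FPKM (-1.02 ± 0.14, adjusted p = 0.0309). PSPH, the phosphatase of the last step, passed over the list alone but not over all genes, at 35.8 and 23.3 FPKM (-0.59 ± 0.16, adjusted p = 0.0989). Neither adjustment called the serine hydroxymethyltransferases SHMT2 (119 and 88.3 FPKM, -0.43 ± 0.13, adjusted p = 0.116) and SHMT1 (19.5 and 22.1 FPKM, 0.19 ± 0.20, adjusted p = 0.562), whose sign turned without wild-type replicate 2 (log2 change -0.06). As a set the list did not pass (median log2 change -0.03, or -0.05 without wild-type replicate 1; camera adjusted p = 0.344).

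Genes of the ATF4 amino acid response were lower as a group. Of 31 tested members, 18 fell and none rose; adjusted over the list alone, 27 fell and none rose, and all 31 estimates were below 0. DDIT3, the stress transcription factor CHOP, fell from 25.4 ± 4.59 to 4.96 ± 0.16 FPKM (SD, n = 2 each; log2 change -2.14 ± 0.16). ATF3 fell from 21.3 to 4.74 FPKM (-1.96 ± 0.25), the pseudokinase TRIB3 from 70.0 to 19.7 FPKM (-1.78 ± 0.10) and STC2, a secreted glycoprotein, from 38.8 to 10.7 FPKM (-1.75 ± 0.18). ASNS, which makes asparagine, fell from 265 ± 30.4 to 92.3 ± 8.78 FPKM (-1.51 ± 0.14, adjusted p = 0.0166). ATF4 itself passed over the list alone but not over all genes, at 348 ± 1.43 and 243 ± 10.5 FPKM (SD, n = 2 each; -0.52 ± 0.10, adjusted p = 0.0624). The list had a median log2 change of -0.79 and was lower than other genes (camera adjusted p = 5.53e-15; adjusted p = 0.236 with an estimated correlation).

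The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were lower as a group by less. Of 20 tested members, 3 fell and none rose; adjusted over the list alone, 12 fell. WARS fell from 119 ± 14.8 to 47.1 ± 6.15 FPKM (SD, n = 2 each; log2 change -1.32 ± 0.15), SARS from 126 to 63.2 FPKM (-0.99 ± 0.10) and CARS from 54.1 to 33.0 FPKM (-0.70 ± 0.10). The median was -0.46 (camera adjusted p = 3.88e-05; adjusted p = 0.806 with an estimated correlation).

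Interferon-induced genes held many of the largest falls. Of 27 tested members, 9 fell and none rose; adjusted over the list alone, 13 fell and 3 rose. OASL, a relative of the 2'-5' oligoadenylate synthetases, was 21.6-fold lower, at 13.9 ± 0.96 FPKM in wild type and 0.641 ± 0.259 FPKM in knockout (SD, n = 2 each; log2 change -3.19 ± 0.18, SE; adjusted p = 0.00726). IFI44 fell from 11.1 to 0.621 FPKM (-2.91 ± 0.22). The antiviral RNA-binding genes IFIT1 and IFIT2 fell from 45.3 to 5.26 FPKM (-2.88 ± 0.13) and from 18.6 to 1.89 FPKM (-2.76 ± 0.13), and IFIT3 from 13.8 to 1.39 FPKM (-2.64 ± 0.15). ISG15, a ubiquitin-like modifier, fell from 253 ± 4.09 to 41.8 ± 1.39 FPKM (SD, n = 2 each; -2.57 ± 0.10, adjusted p = 0.00376). The signalling gene STAT2 (0.65 ± 0.14, adjusted p = 0.0740), chosen after its values were seen, did not pass over all genes and lay above 0. The median of the list was -0.81 (camera adjusted p = 3.02e-04; adjusted p = 0.806 with an estimated correlation).

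Immediate early genes, which respond to growth factors and stress within minutes, were lower as a group. Of 22 tested members, 6 fell and none rose; adjusted over the list alone, 12 fell and 2 rose. FOSL1, a partner of JUN in the AP-1 complex, fell from 106 ± 9.15 to 27.4 ± 1.52 FPKM (SD, n = 2 each; log2 change -1.91 ± 0.12, SE; adjusted p = 0.00869). KLF4 fell from 14.4 to 4.24 FPKM (-1.56 ± 0.13), JUN from 16.6 to 5.56 FPKM (-1.43 ± 0.13) and CYR61, a secreted matrix protein, from 12.7 to 4.78 FPKM (-1.24 ± 0.15). The median was -0.34 (camera adjusted p = 0.0115; adjusted p = 0.806 with an estimated correlation). The call was lost without wild-type replicate 2 (adjusted p = 0.183), with quantile normalization (0.0557) and among genes with a mean of at least 5 FPKM (0.102).

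Proliferation genes were slightly lower as a group. Of 38 tested genes of DNA replication and mitosis, 3 fell and none rose; adjusted over the list alone, 9 fell. CCNE1, the cyclin of entry into S phase, fell from 28.7 ± 0.325 to 13.8 ± 0.308 FPKM (SD, n = 2 each), a 2.08-fold lower level (adjusted p = 0.0213). NDC80, a kinetochore gene, fell from 29.1 to 17.3 FPKM (-0.72 ± 0.13), and CDC20, an activator of the anaphase-promoting complex, from 176 to 112 FPKM (-0.65 ± 0.10). The median was -0.31 (camera adjusted p = 3.71e-05; adjusted p = 0.806 with an estimated correlation), and -0.20 without wild-type replicate 1. Among 28 tested p53 targets 3 fell and none rose, and adjusted over the list alone 7 fell and 2 rose. CDKN1A, which encodes the cell cycle inhibitor p21, fell from 141 to 60.4 FPKM (-1.21 ± 0.10), PMAIP1, which encodes the death effector NOXA, from 88.7 to 35.6 FPKM (-1.29 ± 0.10) and PLK3 from 24.7 to 12.1 FPKM (-0.97 ± 0.15). The p53 list as a set did not pass (median -0.26, camera adjusted p = 0.0591) but did without wild-type replicate 1 (adjusted p = 0.0308), without a filter (0.0155) and among protein-coding genes of at least 1000 nt (0.0487); with an estimated correlation its adjusted p was 0.806.

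WNT targets moved in both directions. Of 17 tested members, 4 rose and 2 fell; adjusted over the list alone, 7 rose and 3 fell. BMP4, a secreted ligand, rose from 62.5 ± 10.7 to 159 ± 6.63 FPKM (SD, n = 2 each; log2 change 1.34 ± 0.15), and NOTUM, an extracellular inhibitor of WNT ligands, from 2.91 to 7.29 FPKM (1.08 ± 0.14). DKK1 fell, as given above, and CCND1, which encodes cyclin D1, fell from 290 to 142 FPKM (-1.03 ± 0.10). The set test put the list above other genes with a median of 0.41 (camera adjusted p = 0.0180; adjusted p = 0.806 with an estimated correlation). That call was lost after removal of the trend with transcript length and GC content (camera adjusted p = 0.115), though the median there was still 0.34.

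Among the pathways next to serine synthesis, purine and pyrimidine synthesis had 30 tested members, none of which passed over all genes or adjusted over the list alone. The list had a median of -0.23 and a camera adjusted p of 0.0332 (adjusted p = 0.806 with an estimated correlation). This call was lost without wild-type replicate 1 (adjusted p = 0.0519), without wild-type replicate 2 (0.0659) and without knockout replicate 2 (0.111). The median was -0.15 without wild-type replicate 1 and -0.12 after removal of the length and GC trend. In glycolysis 1 of 25 members rose and 2 fell, as many rose and 4 fell adjusted over the list alone, and the set did not pass (camera adjusted p = 0.558). The aldolase gene ALDOC rose from 8.90 to 26.4 FPKM (log2 change 1.47 ± 0.13), the glucose transporter gene SLC2A1 fell from 137 ± 35.3 to 49.0 ± 3.83 FPKM (SD, n = 2 each; -1.45 ± 0.20) and the phosphofructokinase gene PFKP fell from 118 to 76.0 FPKM (-0.63 ± 0.10). For this list the median (0.01; -0.05 without wild-type replicate 1) lay above 0 and the mean (-0.11) and the test direction below, and quantile normalization turned the direction. In the sphingolipid and phosphatidylserine list 1 of 25 members fell and none rose, also adjusted over the list alone: SGMS1, a sphingomyelin synthase, from 16.1 to 8.60 FPKM (-0.83 ± 0.12). The set did not pass (median -0.14, or -0.07 without wild-type replicate 1; camera adjusted p = 0.558).

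Glutathione and NRF2 targets went both ways, with 2 of 27 members higher and 4 lower; adjusted over the list alone, 4 rose and 7 fell. The efflux transporter genes ABCC2 and ABCC3 rose from 23.9 to 70.7 FPKM (log2 change 1.53 ± 0.13) and from 6.61 to 18.5 FPKM (1.38 ± 0.20). TXNRD1, the cytosolic thioredoxin reductase, fell from 481 ± 92.8 to 183 ± 17.4 FPKM (SD, n = 2 each; -1.38 ± 0.17), and the ferritin heavy chain gene FTH1 fell by 1.21 ± 0.20. The set did not pass (median -0.20, or -0.11 after removal of the length and GC trend; camera adjusted p = 0.285). In cholesterol synthesis 3 of 25 members rose and none fell, and adjusted over the list alone 6 rose and 2 fell. Among those that rose, TM7SF2, a sterol reductase, went from 15.5 to 28.5 FPKM (0.84 ± 0.11) and SREBF2, the transcription factor of the pathway, from 33.5 to 52.7 FPKM (0.64 ± 0.11). The median of the list (-0.02) lay below 0 and its mean (0.06) and test direction above (camera adjusted p = 0.403); the median turned to 0.13 without wild-type replicate 1 and to 0.07 after removal of the length and GC trend. In fatty acid synthesis 1 of 17 members rose, the desaturase gene SCD, from 252 to 396 FPKM (0.65 ± 0.11); adjusted over the list alone 2 rose and 2 fell, and the set did not pass (median 0.03, or 0.22 without wild-type replicate 1; camera adjusted p = 0.403).

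Nuclear genes of oxidative phosphorylation were lower as a set with no single member passing. Of 45 tested members none rose or fell, over all genes or adjusted over the list alone, and 40 estimates lay below 0. The median was -0.30 (camera adjusted p = 0.00245; adjusted p = 0.806 with an estimated correlation). The call was lost without knockout replicate 2 (adjusted p = 0.0538), with quantile normalization (0.329) and after removal of the length and GC trend (0.147). The list's median log2 difference between wild-type replicates 1 and 2 was 0.32, against 0.09 between the knockout replicates, and its median change was -0.16 without wild-type replicate 1 and -0.12 after removal of the trend. The tested genes with a longest transcript under 1000 nt, 13 of the 45 members among them, had a median log2 change of -0.29. None of the 54 cytosolic ribosomal protein genes passed, over all genes or adjusted over the list alone (median -0.18, camera adjusted p = 0.146), and quantile normalization turned the direction of the list. Its median was 0.002 without wild-type replicate 1 and 0.004 after removal of the trend. It passed without wild-type replicate 2 (adjusted p = 0.00440) and without knockout replicate 1 (0.0364); with all libraries and an estimated correlation its adjusted p was 0.806. None of 27 heat shock and ER chaperone genes passed either, over all genes or adjusted over the list alone (median -0.16, or -0.10 without wild-type replicate 1 and -0.02 after removal of the length and GC trend; camera adjusted p = 0.110), though the set did without wild-type replicate 1 (adjusted p = 0.0270) and without a filter (0.0315); with an estimated correlation its adjusted p was 0.806.

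In the hypoxia list 1 of 25 members rose and 3 fell; adjusted over the list alone, 5 rose and 4 fell. BNIP3L, a receptor for the removal of mitochondria, rose from 10.4 to 22.4 FPKM (log2 change 1.04 ± 0.13). The falls were DDIT4, an inhibitor of mTOR signalling (120 to 37.0 FPKM, -1.67 ± 0.10), VEGFA, an angiogenic growth factor (32.2 to 15.7 FPKM, -0.99 ± 0.12), both also members of the ATF4 list, and SLC2A1, given with glycolysis. The median was 0.18 and the test direction upward, while the mean was -0.003 (camera adjusted p = 0.254). In the lysosome and autophagy list 2 of 31 members rose, NPC2, a cholesterol carrier (53.2 to 118 FPKM, 1.14 ± 0.12), and the peptidase gene TPP1 (15.9 to 27.6 FPKM, 0.76 ± 0.12), and the protease gene CTSL fell from 45.4 to 22.4 FPKM (-0.99 ± 0.10). Adjusted over the list alone 5 rose and 2 fell (median 0.04, or 0.16 without wild-type replicate 1; camera adjusted p = 0.176).

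Markers of cell identity changed in both directions. Of 18 tested epithelial and colon markers 2 rose and 2 fell; adjusted over the list alone, 7 rose and 7 fell. The tight junction genes CLDN3 and TJP3 rose from 7.03 to 17.6 FPKM (log2 change 1.21 ± 0.12) and from 7.21 to 16.0 FPKM (1.05 ± 0.13), while KRT7 fell, as given above, and KRT18 fell from 591 ± 42.6 to 380 ± 0.425 FPKM (SD, n = 2 each; -0.63 ± 0.11). Of 13 tested mesenchymal markers 1 rose and 2 fell; adjusted over the list alone, 5 rose and 3 fell. LOXL2, a matrix crosslinking enzyme, rose from 5.26 to 17.7 FPKM (1.58 ± 0.12), and the receptor kinase gene AXL fell from 27.9 to 13.2 FPKM (-1.03 ± 0.14). Neither set passed (medians -0.21 and 0.001, camera adjusted p = 0.610 and 0.481), the epithelial set turned direction without wild-type replicate 2, and the mesenchymal median was -0.06 without wild-type replicate 1 and 0.08 after removal of the length and GC trend.

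Markers of cell types foreign to the line were mostly below the filter. Of 26 blood and immune markers 3 were tested, and 1 rose, LYZ, which encodes lysozyme, from 0.0843 ± 0.0201 to 2.04 ± 0.55 FPKM (SD, n = 2 each; log2 change 1.48 ± 0.20, adjusted p = 0.0330). Of 20 neural and kidney-line markers 4 were tested, and 1 rose, SYT1, a synaptic vesicle calcium sensor, from 18.9 to 39.5 FPKM (1.02 ± 0.12). Adjusted over the list alone, 2 rose and 1 fell in each of these lists, which were too short for the set test.

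**Figure D2:**
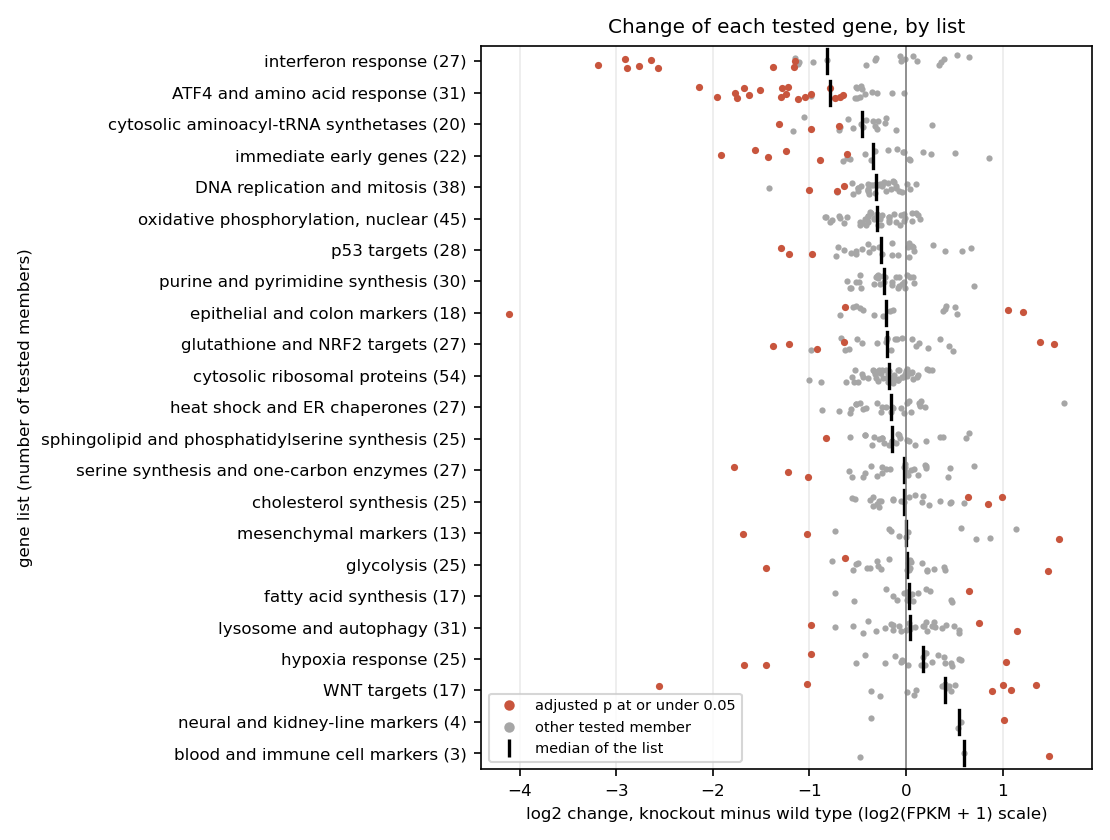
Log2 change from wild type to knockout on the log2(FPKM + 1) scale (horizontal axis) of each tested member of the 23 gene lists (vertical axis, with the number of tested members), sorted by the median, which is drawn as a black bar; vertical scatter within a list only separates the points. Members that passed over all genes are red and the others grey: the ATF4 list has 18 red points, all below 0, around a median of -0.79, and the interferon list has 9, all below 0, around a median of -0.81.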

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

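Removal of the length and GC trend, the restriction to protein-coding genes and the combined omission and scaling of libraries were chosen after seeing the data; the other alternatives were fixed before the data were examined. The direction of all 584 called genes was kept in each setting in which they were tested, and PHGDH passed in every setting except without either knockout library. The number of genes that passed depended on the setting, and the cause was not tested. By construction, fewer libraries or more genes entered in some settings, and the replicate block left fewer residual degrees of freedom. FPKM tables give no counts, so the depth behind a single gene is unknown, and with 2 libraries a group the spread of one group rests on a single difference.

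The counts of genes higher and lower were 1047 and 694 with quantile normalization, 999 and 846 with median-ratio scaling, 878 and 782 after removal of the length and GC trend, 523 and 418 among protein-coding genes of at least 1000 nt, and 955 and 831, or 1409 and 1553, with median-ratio scaling and without wild-type replicate 1 or 2. They were 5 and 12 without a filter, where 26046 genes were tested, and 165 and 133 with a log2 change of at least 1. Leaving out each library gave from 0 to 960 genes higher and from 0 to 2835 lower; a lone library was assumed to vary like the other group, and the wild-type replicates lay farther apart than the knockout replicates (SD of the log2 difference 0.379 and 0.252). Without wild-type replicate 2 the median of all genes was -0.16, against -0.07 with all libraries. PHGDH changed by a log2 of -1.83 to -1.72 over the omitted libraries, with adjusted p of 0.191 and 0.198 without knockout replicate 1 and 2. SHMT1 ran from -0.0633 without wild-type replicate 2, where its sign turned, to 0.45 without wild-type replicate 1.

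With the replicate number as a replicate block, 28 genes were higher and 36 lower, and 62 of the 584 calls were kept. The block takes 1 of the 2 residual degrees of freedom, which by itself can lower the number of calls. The labels do not say whether same-numbered libraries share more than the number. The deviations of same-numbered libraries from their group means correlated across genes with -0.00744, so no shared effect of the number was seen. Because wild-type replicate 1 stood apart, this value cannot exclude a pairing.

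Camera with all libraries called 8 lists. With quantile normalization it called 5, and lost were purine and pyrimidine synthesis (0.810), oxidative phosphorylation (0.329) and immediate early genes (0.0557), while glycolysis (0.810) and ribosomal proteins (0.131) turned direction without passing. After removal of the length and GC trend it called 5, and lost were purine and pyrimidine synthesis (0.0881), WNT targets (0.115) and oxidative phosphorylation (0.147). The median log2 change went from -0.23 to -0.12 for the purine list and from -0.30 to -0.12 for oxidative phosphorylation. For WNT targets it changed less, from 0.41 to 0.34. Purine and pyrimidine synthesis was also lost with median-ratio scaling (0.0522) and, together with immediate early genes (0.102), at a mean of at least 5 FPKM (0.0642). Over the omitted libraries the adjusted p of the purine list ran from 0.0364 to 0.111, that of immediate early genes from 0.00122 to 0.183 and that of oxidative phosphorylation from 1.62e-04 to 0.0538. With median-ratio scaling and without wild-type replicate 2, the purine list (0.192), WNT targets (0.0529) and immediate early genes (0.177) were lost. The epithelial list turned direction without wild-type replicate 2 (0.883; 0.372 to 0.931 over the omitted libraries), the sphingolipid list without knockout replicate 2 (0.344 to 0.953 likewise) and the mesenchymal list without a filter (0.943), none passing. Lists that did not pass with all libraries passed elsewhere in 10 cases, without a change of direction. p53 targets passed without wild-type replicate 1 (0.0308; 0.0322 with median-ratio scaling), without a filter (0.0155) and among protein-coding genes (0.0487). Heat shock and ER chaperones passed without wild-type replicate 1 (0.0270; 0.0216 with scaling) and without a filter (0.0315). Ribosomal proteins passed without wild-type replicate 2 (0.00440; 0.0227 with scaling) and without knockout replicate 1 (0.0364).

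With an estimated correlation 0 lists passed (ATF4 list 0.236, the other 7 lists 0.806). The estimates were -0.024 for the ATF4 list and -0.019 for immediate early genes, below the preset 0.01, so correlation does not explain those 2 losses. For the synthetases the estimate was 0.80. This form of the test rests on 2 residual degrees of freedom. By fry 2 passed, the ATF4 list and the immediate early genes; the synthetases (0.207), purine and pyrimidine synthesis (0.324), DNA replication and mitosis (0.207), interferon response (0.0742), WNT targets (0.353) and oxidative phosphorylation (0.422) did not. The ATF4, synthetase, replication and interferon lists passed in each alternative that kept camera's preset correlation.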

Other observations

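Tests of the length and GC trend, of wild-type replicate 1, of paralog sharing, of gene classes and of depth were chosen after the results were seen, as was a scan of gene families by shared symbol root over 1000 family and direction combinations; the tests of neighbouring genes were set before their result was seen. In that scan (Fisher's exact test, one-sided, Benjamini-Hochberg adjusted) 3 families held more falls than other protein-coding genes. Keratins were lower in 5 of 12 tested members (adjusted p = 0.00372). Beside KRT7 and KRT18 these were KRT80, which fell from 8.72 to 2.42 FPKM (log2 change -1.51 ± 0.14), KRT81, at 2.30 and 2.33 FPKM in wild type against 0 and 0.111 FPKM in knockout, and KRT17, at 1.29 and 1.28 against 0 and 0.187 FPKM. In the other direction 2 of the 12 rose, KRT13 from 0.238 to 3.87 FPKM (1.98 ± 0.20) and KRT23 from 4.81 to 14.4 FPKM, 2.98-fold (adjusted p of the family for rises = 1). Of the other abundant keratins, KRT8 (-0.48, adjusted p = 0.0754) and KRT19 (-0.17, adjusted p = 0.336) did not pass over all genes. Of 4 tested CXCL chemokine genes 3 fell (adjusted p = 0.0144), CXCL8 from 3.02 to 0.434 FPKM (-1.48 ± 0.21), CXCL1 from 1.92 to 0.294 FPKM (-1.16 ± 0.20) and CXCL10, at 1.62 and 1.88 FPKM in wild type against 0.0821 and 0 FPKM in knockout. IFIT genes fell in 3 of 4 members (adjusted p = 0.0144). CXCL8, CXCL1, CXCL10, KRT81 and KRT17 met the filter only through the wild-type libraries, with both knockout values below 1 FPKM. Such genes were more apt to be called as falls than as rises. KRT13 met it only through the knockout libraries. A value of 0 FPKM can stand for a gene missing from a library. Fisher's test treats the members of a family as independent, although IFIT1, IFIT2 and IFIT3 share a joint locus, as do KRT7 and KRT81. These counts rest on calls made with all libraries, none of which held without knockout replicate 1 or without knockout replicate 2.

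Single genes outside the lists moved too. ID1 rose from 195 to 484 FPKM (2.48-fold) and the inhibitory SMAD6 from 0.853 to 6.31 FPKM (1.98 ± 0.16), while SMAD7 fell from 3.5 to 1.07 FPKM (-1.12 ± 0.16); ID2 did not pass (0.69, adjusted p = 0.0587). The related nuclear receptor genes NR2F1 and NR2F2, each sharing a joint locus with an antisense gene, went apart, at 19.2 and 76.1 FPKM (1.94 ± 0.17) against 25.8 and 13.1 FPKM (-0.92 ± 0.12). These genes were chosen after their values were seen and stand for no tested group.

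Interferon-response genes were lower in the knockout, with 9 of 27 called. After removal of the length and GC trend the list's median was -0.73 and all 9 genes still passed, and without wild-type replicate 1 the median was -0.70, so neither accounts for the fall as a whole. The 70 tested neighbours of the called genes, on 6 chromosomes, had a median log2 change of -0.0188 (bootstrap SE 0.0571). This argues against loss of most of these regions together. The pooled median cannot exclude loss of a single region. No test here addressed a biological explanation, and the knockout stays confounded with any difference between clones or cultures.

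APOBEC3C, APOBEC3F and APOBEC3G, neighbours on chromosome 22, rose by a log2 of 2.01 to 2.74, while APOBEC3B did not pass (0.15 ± 0.15, adjusted p = 0.536); the family's excess did not pass the scan (adjusted p = 0.0759). The 20 tested neighbours of the cluster had a median log2 change of -0.0136 (bootstrap SE 0.115), which argues against a gain that reaches most of them. A gain confined to the APOBEC3 genes or to a few neighbours would not move this median. After removal of the length and GC trend the smallest of the 3 changes was 2.07 (SE 0.111). At most 5.98% of the 75-mers of APOBEC3C or APOBEC3G occurred exactly in another APOBEC3 gene, which argues against identical stretches as the source of their rise. Near matches were not counted, and how reads were assigned is not known. For APOBEC3F the share was 16.5%, and part of its rise could come from reads of the others. No test here addressed a biological explanation, and the knockout stays confounded with any difference between clones.

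Wild-type replicate 1 stood apart from the other libraries. In median-ratio scaling its log2 factor was 0.15, against -0.07 to -0.01 in the other libraries, so a difference of scale was present. A single scale factor would move all gene classes alike. After that scaling, 110 short non-coding genes were compared with 6492 long protein-coding genes, all with a mean of at least 5 FPKM. In wild-type replicate 1 relative to 2, the short genes lay above the long ones by a median log2 of 0.47 (bootstrap SE 0.113). Between the knockout replicates the difference was 0.10. A single scale factor was therefore not the whole of the difference. The implied depth of wild-type replicate 1, 20.3 M fragments by a rough estimate from low values, lay within the range of the others. Among 8513 protein-coding genes of at least 2500 nt the spread of the wild-type replicate difference was 1.2 times that of the knockout (bootstrap SE 0.0220). The SDs there were 0.272 and 0.226, and over all tested genes the ratio was 1.5. An excess thus remained among long coding genes. It did not clear the bound set for this test, a ratio above 1.2 by more than 2 SE. Whether short transcripts were the whole of the difference therefore stayed undecided. The ratio also rests on a single replicate difference per genotype. The labels give no library batch, and no biological explanation was tested.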
